A study of Homo sapiens with 14 samples.

How the data were processed

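H3K4me2 ChIP-seq was done in MDA-MB-231 cells treated with OICR-9429 or DMSO for 24 to 96 hours, with 5% Drosophila chromatin added as a spike-in before the antibody, per the labels' protocols. The series also holds input libraries (3 DMSO, 3 OICR-9429 and 1 untreated) and 1 untreated ChIP library, which were not analysed here. The deposited table holds raw read counts, not normalised, for 6 ChIP libraries over 1 common set of 54942 regions on chromosomes 1 to 22 and X. Per the submitters' processing notes, the authors used Bowtie, MACS2, deepTools, featureCounts and DESeq2 and the builds hg38 and dm6. Versions, settings, duplicate removal and the merging of peaks are not given in the sources used here. All libraries were counted over this common set, and regions are limited to what the authors' peak calling found. Spike-in factors were not used here, so fold changes are relative to all regions and a shift shared by all of them cannot be seen.

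Groups and replicate numbers came from the labels. Regions were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, glmQLFit with robust estimation, glmQLFTest, Benjamini-Hochberg adjustment over 51156 tested regions, threshold 0.05), with 3 DMSO against 3 OICR-9429 libraries and no covariate. The standard error of a log2 fold change is its size divided by the square root of F. Normalised CPM are counts scaled to the TMM library sizes and are given as mean ± SD of 3 libraries. Depth was 16483098 to 23509413 counts per library, over 99% of them in tested regions.

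Regions were assigned with a table of RefSeq genes of the GRCh38.p14 assembly, the same build as hg38. The table gives gene spans without strand, exons or sequence, so transcription start sites could not be placed. In place of promoters, a region within 1 kb of either end of a protein-coding gene was called a gene-boundary region. The other regions overlapping a protein-coding gene were called inside a gene, and the rest between genes. A region between genes can therefore lie in a gene that is not protein-coding. A boundary region can therefore lie at the 3' end of a gene, and exons and introns were not told apart. Of 20037 protein-coding genes 13595 had a boundary region, and for 73.9% of these it lay at 1 end only. A region outside boundaries took the name of the gene that holds it or of the nearest gene within 100 kb. Class shares were compared with an exact two-sided permutation test, which cannot go below 0.1 with 3 against 3 libraries.

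The 21 gene lists, 908 genes in all with 21 of them in more than 1 list, were written before the data were examined, as were the designs, the alternatives and the rule for named genes. They are cytosolic ribosomal proteins, mesenchymal and EMT, epithelial, luminal breast, basal breast, H3K4 methylation machinery, HOX, cell cycle, p53 and apoptosis, interferon, NF-kB, AP-1, Hippo, MYC and ribosome biogenesis, cholesterol and fatty acid synthesis, hypoxia and glycolysis, unfolded protein and ATF4, oxidative stress, haematopoietic, neuronal, and endothelial and fibroblast genes. Each gene was represented by its boundary region with the highest mean count, and each region entered a list once. Lists were tested with limma 3.58.1 (cameraPR on the fitted log2 fold changes, preset correlation 0.01) against all 10894 such regions, again with a correlation estimated per list (0.07 to 0.85), and with fry. The per-list correlation was estimated from the TMM values, also where the fold changes came from loess offsets. Unlike cameraPR, fry makes no comparison with other regions. Several genes can share a region, and their values are then the same.

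Named genes are, first, the 10 most negative and 10 most positive log2 fold changes among annotated regions with an adjusted p under 0.05, groups that do not overlap and at least median normalised counts, each gene once. They are, second, members of each list with the smallest p, and last WDR5, KMT2A, VIM, ZEB1, CDH1, MYC, EGFR, RPL3, GAPDH and ACTB whatever their values. Some listed genes that meet this rule are not reported here.

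Alternatives were library totals, DESeq2 size factors, loess offsets (span 0.3) that remove the trend of log counts on mean abundance per library, no count filter, a mean count of at least 50, each library left out, DESeq2 1.42.0 with its Wald test, the replicate number as a block, an adjusted p under 0.01, a test against a fold of 1.2, no robust estimation, other class definitions, and other list tests. For library size, each library's log2 CPM minus the mean of the 6 libraries was fitted on mean abundance. The slope of that fit was regressed on group and log2 library total, over all 6 libraries and with each left out. Counts simulated from the means and library sizes of these 6 libraries tested the scripts. Among 50999 regions 200 were changed, and a simulated list was shifted as a whole. In this simulated comparison of OICR-9429 and DMSO, edgeR with TMM recovered 87% of changes of log2 1 and 14% of changes of log2 0.5, and 5.88% of its calls were false. The simulation held no trend of fold change with abundance and far fewer changed regions than were called in the data. These percentages therefore need not hold for the data. No 2 libraries held identical counts, and every pair differed by more than sampling noise (chi-square per degree of freedom of at least 1.54).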

Results

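H3K4me2, a histone mark of promoters and of distal regulatory elements, was profiled by ChIP-seq in MDA-MB-231, an established triple-negative breast cancer line. Cells received OICR-9429, a small molecule that blocks WDR5, or the solvent DMSO. WDR5 is a shared subunit of the enzyme complexes that methylate H3K4. Treatment lasted between 24 and 96 hours, per the labels, with no time given per library. The comparison covered 3 DMSO and 3 OICR-9429 ChIP libraries, each counted over the same 54942 regions. Counts per library were 17150428, 16607971 and 18524206 for DMSO replicates 1 to 3. For OICR-9429 replicates 1 to 3 they were 23509413, 18538814 and 16483098. The titles number the libraries as biological replicates, without saying how the cultures were kept apart, and the p-values rest on the spread between them. All coordinates are hg38, and every value of a group below is over 3 libraries.

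The question put by the design was how WDR5 blockade changes H3K4me2 across the genome. With OICR-9429 a larger share of the counts lay at gene boundaries and a smaller share in distal regions. Regions within 1 kb of either annotated end of a protein-coding gene held 48.8% ± 2.53 (SD, n = 3) of the counts with DMSO and 54.4% ± 2.19 (SD, n = 3) with OICR-9429. Regions inside genes held 28.3% ± 1.59 with DMSO and 25.2% ± 1.17 with OICR-9429, and regions between genes 22.8% ± 0.949 and 20.5% ± 1.03. All 3 OICR-9429 libraries lay above all 3 DMSO libraries in the boundary share, between 52.8% and 56.9% against 46.6% to 51.6%. The exact two-sided permutation test gave p = 0.1 for each class, the smallest p that 3 against 3 libraries can give, so this difference could not pass a threshold of 0.05.

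**Figure D1:**
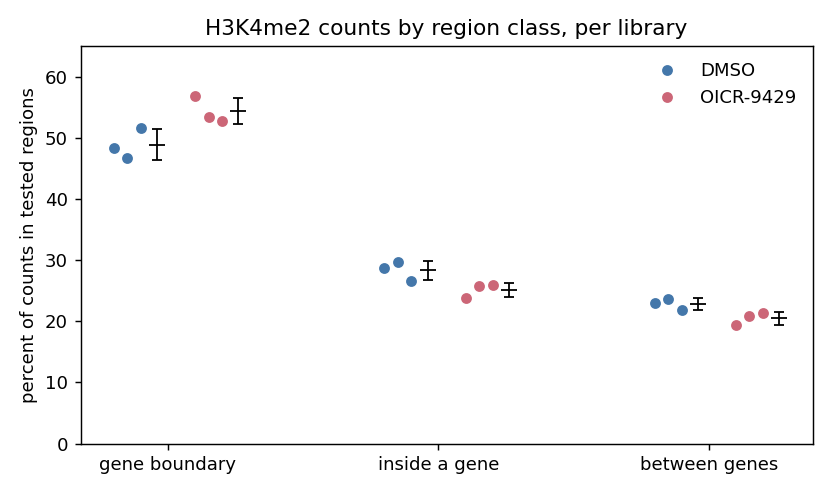
Percent of each library's counts in tested regions that fell at gene boundaries, inside genes and between genes. Points are libraries and the black marks are the mean ± SD of 3 libraries; the OICR-9429 libraries lie between 52.8% and 56.9% at gene boundaries and the DMSO libraries between 46.6% and 51.6%.

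Region by region, edgeR's quasi-likelihood test with TMM scaling called 7179 of 51156 tested regions lower and 8709 higher with OICR-9429 at an adjusted p under 0.05. At gene boundaries 5928 regions were higher and 422 lower, with a median log2 fold change of 0.36. Inside genes 3872 were lower and 1533 higher (median -0.09), and between genes 2885 were lower and 1248 higher (median -0.06). The split depended on the scaling. With library totals in place of TMM, 11984 regions were lower and 3301 higher, and the median of all regions moved from 0.03 to -0.17. With loess offsets, which remove the trend of fold change with region strength, 4553 were lower and 2794 higher, and the boundary median fell to 0.11. A set of 3275 regions was lower and 1067 higher under all 4 scalings, a set chosen after seeing the data. Of these lower regions 1918 lay inside genes, 1153 between genes and 204 at gene boundaries, while 677 of the higher regions lay at gene boundaries.

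These scalings are relative: a gain or loss shared by all regions cannot be seen, because the factors of the Drosophila spike-in were not used here. Single libraries also mattered. Without DMSO replicate 1 the calls were 4366 lower and 1165 higher, and without DMSO replicate 2 they were 4096 lower and 1104 higher. The higher calls numbered 5263 without OICR-9429 replicate 1 and 4503 without OICR-9429 replicate 2. At gene boundaries they were 746, 649, 3023 and 3220 in the same order.

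**Figure D2:**
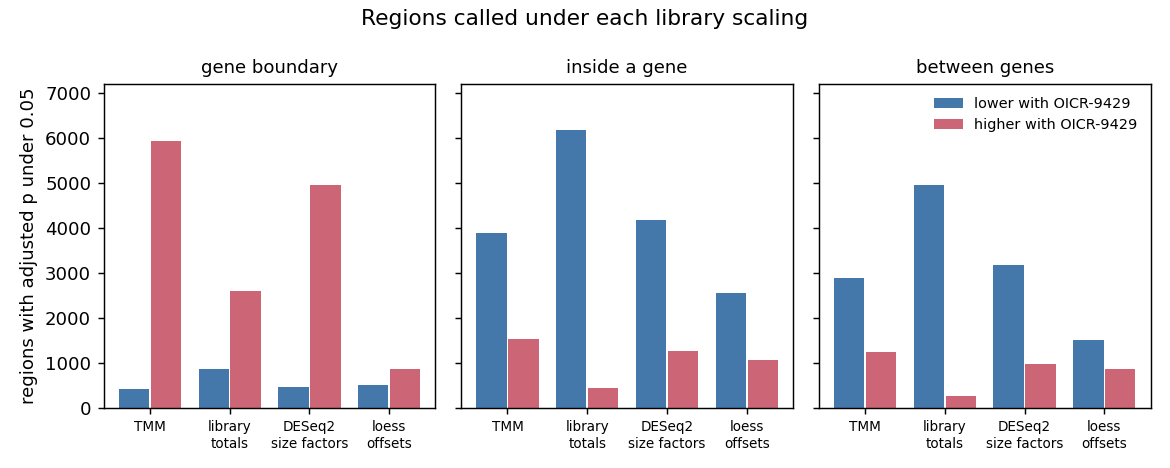
Number of regions called lower (blue) and higher (red) with OICR-9429 at an adjusted p under 0.05, by region class and by library scaling. At gene boundaries higher calls range from 5928 with TMM to 863 with loess offsets, while inside genes and between genes lower calls exceed higher calls under each of the 4 scalings.

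The largest changes of regions with at least median counts lay mostly outside gene boundaries. Of all tested regions, 12311 of 51156 lay at gene boundaries. That share is not the background of these picks, because stronger regions lay at boundaries more often. It ran from 10.9% in decile 6 of abundance to 73.5% in decile 10. Of the 10 largest falls, 7 were inside genes and 3 at gene boundaries, with folds between 2.26 and 2.91. Counts in a region inside TRPC4AP (chromosome 20, 35052267 to 35054010) fell from 15.1 ± 1.51 to 5.20 ± 1.24 normalised CPM (counts scaled to the TMM library size; log2 fold change -1.54, SE 0.17, adjusted p = 0.000212). A region at a boundary of PKD1L3 (chromosome 16, 71922592 to 71929213) fell from 19.0 ± 2.66 to 7.18 ± 0.327 (log2 fold change -1.41, adjusted p = 0.000165). LRP5, which encodes a Wnt co-receptor, held a strong region (chromosome 11, 68335985 to 68343291) that fell from 38.0 ± 5.62 to 16.0 ± 1.47 normalised CPM. SMAD6 encodes an inhibitor of BMP signalling, and a region inside it (chromosome 15, 66761141 to 66764014) fell from 18.1 ± 1.18 to 7.90 ± 1.03. The other falls were inside BCAR3 (log2 fold change -1.36), EPS15L1 (-1.31), DNAJB6 (-1.19) and CASZ1 (-1.18), and at boundaries of EXOSC7 (-1.25) and ITGA10 (-1.17).

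Among the 10 largest rises, 6 were inside genes, 2 between genes and 2 at gene boundaries, with folds between 1.92 and 2.72. A region inside KCP, whose product is a secreted modulator of BMP signalling, rose from 13.5 ± 2.87 to 36.7 ± 3.90 normalised CPM (chromosome 7, 128902782 to 128904586, log2 fold change 1.44, SE 0.16, adjusted p = 0.000212). A region at a boundary of SERINC3 (chromosome 20, 44495618 to 44497189) rose from 8.41 ± 2.18 to 20.4 ± 1.44. Between genes, the region nearest PAG1 (chromosome 8, 80964369 to 80966258) rose from 7.09 ± 0.569 to 16.3 ± 1.63, and the region nearest EFR3A had a log2 fold change of 1.09. The other rises lay inside LRRC8E (1.11), KIFC3 (1.07), ATP9A (1.07), DGKI (1.05) and SP140 (1.03) and at a boundary of VAC14 (0.94). These 20 regions had adjusted p up to 0.00309, and all 20 were called the same way under each of the 15 other settings run for single regions. The ITGA10 and VAC14 regions also touched a boundary of another protein-coding gene.

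**Figure D3:**
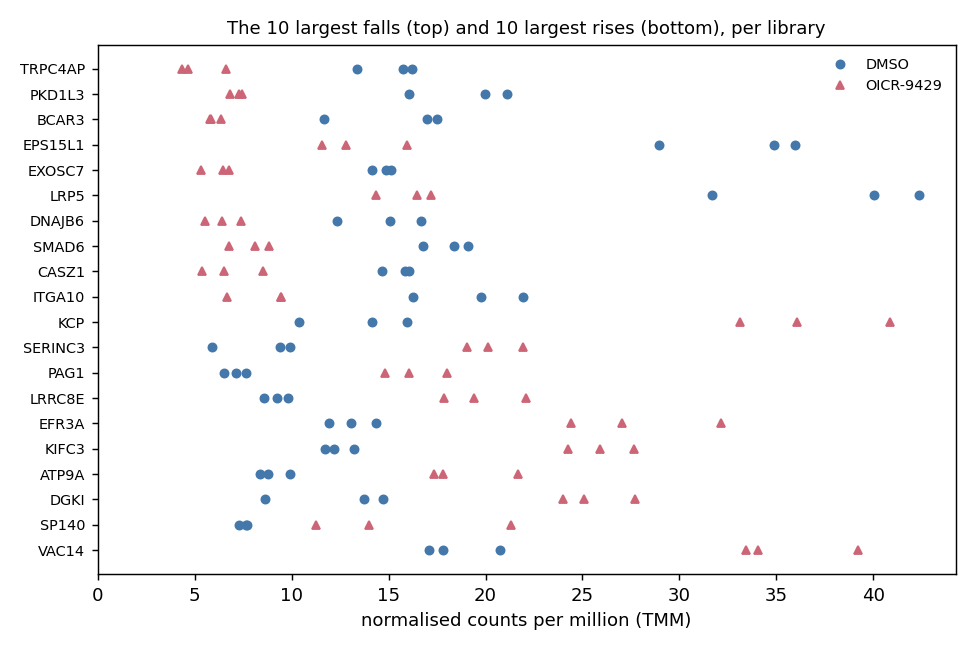
Normalised CPM (TMM) of the regions with the 10 largest falls and the 10 largest rises, 1 row per region named by its gene. Each point is 1 library (3 DMSO, 3 OICR-9429), and the groups do not overlap in any row because the regions were chosen to have separate groups.

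Groups of genes were compared at their boundary regions, of which 10894 entered the comparison: 52.2% of these were called higher and 2.20% lower, with a median log2 fold change of 0.37. Each of 21 lists was therefore set against the other boundary regions. Epithelial genes stood lowest, though with TMM hardly under endothelial and fibroblast genes (differences -0.2397 and -0.2366). Of their 43 regions 6 were lower and 11 higher (8 and 13 adjusted over the list alone), and their mean log2 fold change lay 0.24 under that of other boundary regions (difference -0.24, camera adjusted p = 1.38e-05). The list's own median was 0.18 with TMM and -0.13 with loess offsets, so whether the list as a whole stood above or under 0 depended on the scaling. The call was lost with an estimated correlation between genes (adjusted p = 0.959). Counts at a boundary of CDH1, which encodes the adherens junction protein E-cadherin, fell from 13.9 ± 1.84 to 8.59 ± 0.955 normalised CPM (chromosome 16, 68737082 to 68738350, log2 fold change -0.69, SE 0.15, adjusted p = 0.00601). The tight junction gene TJP3 fell by 0.74 on the log2 scale and ELF3, an epithelial transcription factor, fell by 0.74 (adjusted p = 0.00494 and 0.00667). These 3 calls held under the 4 scalings.

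Luminal breast genes had 1 lower and 9 higher among 25 regions (1 and 9 adjusted over the list alone), with no call for the list (difference -0.13, camera adjusted p = 0.14, and 0.049 without OICR-9429 replicate 1). The lower region lay at SPDEF, a transcription factor of luminal cells, where counts fell from 60.8 ± 7.15 to 31.4 ± 6.30 normalised CPM (chromosome 6, 34554006 to 34556964, log2 fold change -0.95, adjusted p = 0.00115). Mesenchymal and EMT genes had 3 lower and 25 higher among 47 regions (3 and 28 adjusted over the list alone; difference -0.05, adjusted p = 0.328). The smooth muscle marker TAGLN fell by 0.89 (SE 0.14, adjusted p = 0.000992), in a region that also touched another gene, while CCN1 and CD44 rose by 0.65 and 0.56 (0.32 and 0.22 with loess offsets). Basal breast genes had 1 lower and 14 higher among 32 regions (1 and 18 adjusted over the list alone; difference -0.05, adjusted p = 0.378), among them MYC, which rose from 100.0 ± 18.6 to 151 ± 8.20 normalised CPM (log2 fold change 0.60, adjusted p = 0.00652; 0.27 with loess offsets, and 0.44 to 0.76 with 1 library left out). Endothelial and fibroblast genes, a check for other cell types, had no called region among 12. Their list was called lower (difference -0.24, adjusted p = 0.0352), a call lost with an estimated correlation (adjusted p = 0.406), with loess offsets (adjusted p = 0.212), with no count filter (0.0770), with a mean count of at least 50 (0.0714), without DMSO replicate 2 (0.0842) and without OICR-9429 replicate 3 (0.0817). Its members with the smallest p were ESAM (0.24), KDR (0.31) and ROBO4 (0.22), with ESAM and ROBO4 at -0.09 and -0.12 under loess offsets.

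Among growth and metabolism genes many boundaries were higher, but with TMM and all libraries no list differed from other boundaries past the threshold. Targets of MYC and genes of ribosome biogenesis had 38 higher and 0 lower among 46 regions (43 and 0 adjusted over the list alone). Their difference from other boundaries, 0.12, missed the threshold (camera adjusted p = 0.0578) and passed it without DMSO replicate 1 (0.048), OICR-9429 replicate 1 (0.049) or OICR-9429 replicate 2 (0.0318). These values use the preset correlation, and with an estimated correlation and all libraries the camera adjusted p was 0.959. The arginine methyltransferase gene PRMT5 rose by 0.59 and UBTF, a factor of ribosomal RNA transcription, by 0.62 (adjusted p = 0.00498 and 0.00612; 0.26 and 0.29 with loess offsets). Cytosolic ribosomal protein genes had 46 higher and 0 lower among 75 regions (57 and 0 adjusted over the list alone; difference 0.06, adjusted p = 0.26), including RPL41 at 0.68 and RPS16 at 0.59. The ribosomal difference turned to -0.03 with loess offsets. Cholesterol and fatty acid synthesis genes had 22 higher and 0 lower among 33 regions (26 and 0 adjusted over the list alone; difference 0.10, adjusted p = 0.158), and INSIG1, a sterol sensor, rose from 75.6 ± 7.31 to 126 ± 16.1 normalised CPM. Hypoxia and glycolysis genes had 26 higher and 0 lower among 39 regions (29 and 0 adjusted over the list alone; difference 0.09, adjusted p = 0.158), with HILPDA higher by 0.65. Cell cycle genes had 33 higher and 0 lower among 60 regions (38 and 0 adjusted over the list alone; difference 0.00, adjusted p = 0.952). Their leading members CCNE2 (0.57) and CDK4 (0.55) lost their calls with loess offsets and without DMSO replicate 1 or 2.

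None of the stress and signalling lists passed the threshold in this fit either. Genes of the unfolded protein and ATF4 response had 28 higher and 1 lower among 35 regions (31 and 1 adjusted over the list alone; difference 0.09, adjusted p = 0.158). TRIB3, a stress-induced pseudokinase gene, rose by 0.75 (SE 0.14, adjusted p = 0.00263), and the lower region was a weak one at PDIA6, which fell from 5.91 ± 0.808 to 2.68 ± 0.736 normalised CPM. AP-1 and immediate early genes had 32 higher and 0 lower among 44 regions (37 and 0 adjusted over the list alone; difference 0.12, adjusted p = 0.0825), led by the orphan nuclear receptor gene NR4A2 (0.87, adjusted p = 0.00228). NF-kB and inflammatory genes had 16 higher and 0 lower among 32 (21 and 0 adjusted over the list alone; difference 0.06, adjusted p = 0.328), with LIF higher by 0.65. In the p53 target and apoptosis list 18 of 39 were higher and 0 lower (25 and 0 adjusted over the list alone; difference 0.06, adjusted p = 0.324), among them BCL2L11, which encodes the pro-apoptotic protein BIM (0.80). Xenobiotic and oxidative stress genes had 19 higher and 0 lower among 30 (22 and 0 adjusted over the list alone; difference 0.08, adjusted p = 0.26), with the ferritin gene FTH1 higher by 0.61. Interferon response genes had 13 higher and 2 lower among 46 (13 and 2 adjusted over the list alone; difference -0.09, adjusted p = 0.158), and OAS1 fell by 0.73 (adjusted p = 0.0073). Hippo pathway targets had 16 higher and 1 lower among 29 (18 and 1 adjusted over the list alone; difference -0.02, adjusted p = 0.864), the lower one being CRIM1 at -0.48 (adjusted p = 0.0112).

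Genes of the H3K4 methylation machinery had 20 higher and 0 lower among 29 regions (24 and 0 adjusted over the list alone; difference 0.11, adjusted p = 0.151), led by the demethylase gene KDM5C at 0.65 and the methyltransferase gene SETD7 at 0.58. HOX genes and their cofactors, classical targets of WDR5 complexes, had 9 higher and 0 lower among 18 (10 and 0 adjusted over the list alone; difference -0.09, adjusted p = 0.26). PBX3 had a log2 fold change of 0.55, a call lost with loess offsets and without DMSO replicate 1. Haematopoietic genes had 5 higher and 0 lower among 13 (6 and 1 adjusted over the list alone; difference -0.12, adjusted p = 0.208) and neuronal genes 3 higher and 0 lower among 11 (6 and 0 adjusted over the list alone; difference -0.02, adjusted p = 0.894). At WDR5 itself the log2 fold change was 0.42 (adjusted p = 0.0261) and at KMT2A, a methyltransferase that binds WDR5, 0.42 (adjusted p = 0.0268). The mesenchymal genes VIM and ZEB1 stood at 0.46 and 0.36, EGFR at 0.37, and the housekeeping genes RPL3, GAPDH and ACTB at 0.54, 0.52 and 0.43 (adjusted p between 0.0115 and 0.0435). These 8 genes passed the threshold with TMM, had loess values between 0.03 and 0.21 that did not pass, and lost their calls without DMSO replicate 1 or 2. WDR5, KMT2A, ZEB1, EGFR and ACTB also lost theirs with library totals and without OICR-9429 replicate 1. KMT2A, ZEB1 and EGFR lost theirs without OICR-9429 replicate 2, KMT2A and ZEB1 without OICR-9429 replicate 3, and ACTB without OICR-9429 replicate 2 or 3. ACTB also lost its call with DESeq2 size factors (adjusted p = 0.0583), so of the 4 scalings it passed with TMM alone. Their values, 0.36 to 0.54 beside a boundary median of 0.37, stayed above 0 under all 4 scalings.

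No list was called with an estimated correlation (smallest adjusted p = 0.406), nor by fry, which tests whether a list moves on balance one way (smallest adjusted p = 0.0572, 14 lists at an unadjusted p under 0.05). In fry's mixed test, which counts changes in either direction, 19 of the 21 lists passed. As fry does not set a list against other boundary regions, of which 52.2% were called higher, this count does not single out these lists. With loess offsets no list had more than 8 higher or 7 lower regions. The epithelial difference was then -0.23 (camera adjusted p = 2.01e-07), with 7 lower and 1 higher region. Its camera adjusted p was 0.978 with an estimated correlation. That correlation came from the TMM values, which still held the abundance trend, and none was estimated with the trend removed. With all regions of a gene summed, 6 lists were called higher: MYC targets and ribosome biogenesis (adjusted p = 0.00148), unfolded protein and ATF4 response (0.00365), H3K4 methylation machinery and hypoxia and glycolysis (0.0143 each), p53 targets and apoptosis (0.0229), and AP-1 and immediate early genes (0.0472). The summed test set each list against all genes with a region, including genes with no boundary region. In the MYC list 49 of 49 members had a boundary region, and in the H3K4 machinery list 29 of 32. These 6 calls may therefore reflect the rise of boundary regions as a class, which was not tested. At boundary regions, DESeq2's Wald test called the MYC target list higher (camera adjusted p = 0.0451). For the genes named above as list members with the smallest p, called rises were smaller with loess offsets than with TMM, between 0.22 and 0.56. This did not hold for every member chosen by that rule, as some that are not named here rose more with loess offsets. Regrouping the 6 libraries called up to 6 lists with the preset correlation. Of the genes named for their lists, CCN1, RPL41, RPS16, CCNE2, CDK4, PDIA6, FTH1, KDM5C, ESAM, RGS5 and TAGLN share their region with a boundary of another protein-coding gene, as does GAPDH. KDM5C lies on chromosome X, whose regions were higher as a whole (median log2 fold change 0.20).

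**Figure D4:**
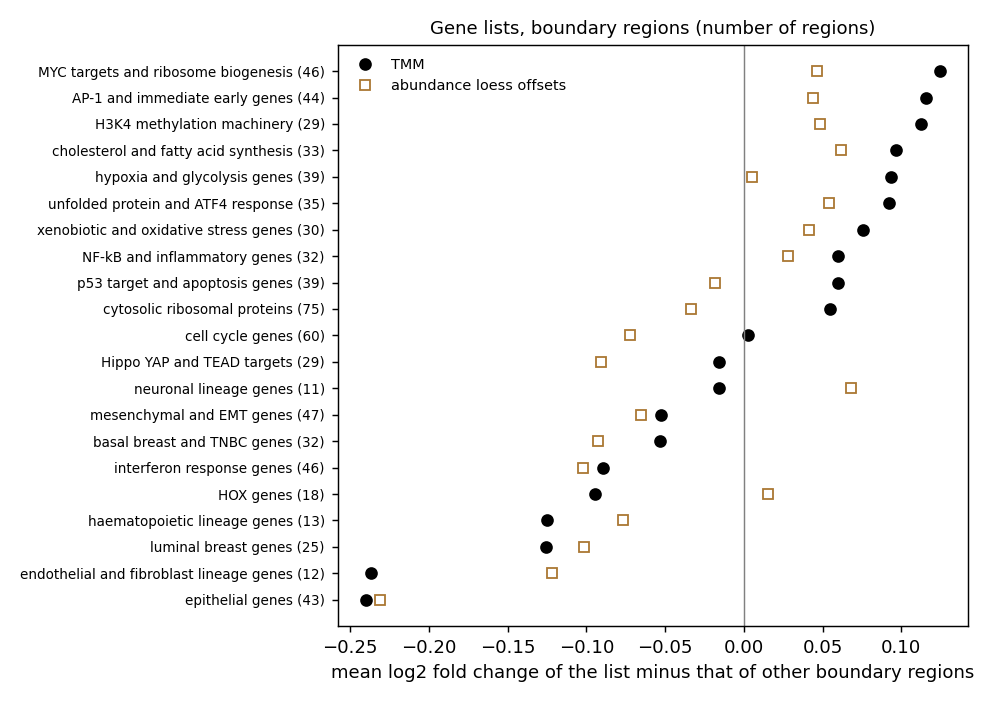
Mean log2 fold change (OICR-9429 minus DMSO) of each list's boundary regions minus that of the other boundary regions, with TMM (filled) and with loess offsets (open squares); the number of regions is in parentheses. Epithelial genes lie lowest under both, at -0.24 and -0.23, with endothelial and fibroblast genes also at -0.24 with TMM.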

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

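Alternatives added after seeing the data are the set shared by all 4 scalings, loess offsets for class counts, loess offsets combined with the replicate block or with an estimated correlation, and sums over distal regions; the other settings were planned. No setting called a region in the opposite direction to the TMM fit. The corrections for GC content, with and without the block, were not run, since no genome sequence was used. The cause of the shifts below was not tested, except that a lower p threshold and the set shared by all 4 scalings lower a count by construction.

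Against 7179 lower and 8709 higher regions, library totals gave 11984 and 3301, loess offsets 4553 and 2794, the fold test 2989 and 986, an adjusted p under 0.01 2638 and 1472, and all 4 scalings together 3275 and 1067. A mean count of at least 50 gave 5073 higher. Leaving out 1 library gave 4096 to 8234 lower and 1104 to 12192 higher. Same-numbered libraries did not deviate together (correlations -0.16, 0.18 and -0.19), and not every library correlated best with its own number. With so few libraries per group these values cannot exclude shared cultures or days, so whether the numbers pair the samples stays open. The replicate block gave 5826 lower and 6333 higher, and with loess offsets 2478 and 929.

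At gene boundaries library totals gave 858 lower and 2595 higher, loess offsets 863 higher, a mean count of at least 50 3791 higher, and boundaries of all genes 994 lower; leaving out 1 library gave 285 to 680 lower and 649 to 8545 higher. Inside genes library totals gave 6178 lower and 439 higher, loess offsets 2547 lower, no filter 1001 higher, a mean count of at least 50 721 higher; leaving out 1 library gave 2107 to 4306 lower and 260 to 1931 higher. Between genes library totals gave 4948 lower and 267 higher, loess offsets 1508 lower, no filter 729 higher, a mean count of at least 50 561 higher, and boundaries of all genes 1908 lower and 636 higher; leaving out 1 library gave 1702 to 3285 lower and 159 to 1716 higher. The group differences in class share moved by less than 1 SD under every setting run, with a boundary difference of 4.26 to 6.90 percentage points when 1 library was left out.

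Lists called lower numbered 2 with TMM. They were 1 with loess offsets, with no filter, with a mean count of at least 50 and with loess offsets plus the replicate block. With 1 library left out they were 1 to 3. They were 0 with fry, with distal sums under either scaling, and with an estimated correlation for the fold changes of either scaling. That correlation came from the TMM values in both cases. Lists called higher were 0 with TMM, 0 to 1 with 1 library left out and 1 with DESeq2's test. They were 6 with all regions of a gene summed, a test against all genes with a region. The block alone changed no list call.

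Differences of uncalled lists changed sign with loess offsets. With these alone, and the same with an estimated correlation, they were -0.0332 for ribosomal proteins, 0.0156 for HOX genes, -0.0722 for cell cycle genes, -0.0183 for p53 targets and 0.0681 for neuronal genes. With the replicate block added they were -0.0321, 0.0157, -0.071, -0.0184 and 0.0759. Cell cycle genes were at -0.00519 with a mean count of at least 50. With 1 library left out cell cycle genes ranged from -0.0156 to 0.0259, Hippo targets from -0.0505 to 0.0277 and neuronal genes from -0.0462 to 0.0574. Among 109 named regions, ESAM, ROBO4 and RGS5, none of them called, turned to -0.0931, -0.118 and -0.119 with loess offsets and to -0.0945, -0.119 and -0.121 with the block added. Calls were lost by 35 named regions with loess offsets, 64 with loess offsets plus the replicate block, 8 with library totals, 32 without DMSO replicate 1 and 36 without DMSO replicate 2. In counts simulated at this depth, 14% of the changes of log2 0.5 were recovered. That simulation had 200 changed regions, a shifted list and no abundance trend, so the percentage need not hold for the data.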

Other observations

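Tests chosen after the result was seen are those of the TMM calls against other splits, of library size and of the abundance trend on chromosome X, and the sums over distal regions. The regions of a gene that touch no boundary, inside it or nearest to it within 100 kb, were summed for 10429 genes. Of these sums 1191 were lower and 944 higher. Among 27 epithelial genes with such regions 10 were lower and 0 higher, and 5 of 21 ribosomal protein genes were lower and 0 higher. Endothelial and fibroblast genes had 5 lower and 2 higher among 21, and HOX genes 5 lower and 1 higher among 14. AP-1 and immediate early genes had 8 higher and 1 lower among 34, cholesterol and fatty acid synthesis genes 7 higher and 2 lower among 25, and hypoxia and glycolysis genes 6 higher and 1 lower among 27. No list was called against the other genes (epithelial difference -0.12, camera adjusted p = 0.518).

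With loess offsets chromosome X stood apart from the autosomes. With TMM, 391 of its 1286 tested regions were higher and 86 lower, with a median log2 fold change of 0.20. Chromosome 19 had a higher TMM median, 0.23, with 580 of 2099 regions higher and 177 lower. With loess offsets the median of chromosome X was 0.21, against -0.03 to 0.10 over the autosomes. A positive value was then found in 75.2% of chromosome X regions against 51.8% on the autosomes. On chromosome X the lowest OICR-9429 library lay 0.16 above the highest DMSO library (exact two-sided permutation p = 0.1, the smallest possible). The value of 0.21 with the trend removed argues against the abundance trend as the cause. More chromosome X DNA in the OICR-9429 cultures may account for it: boundary and distal regions stood 0.28 and 0.15 higher, a difference of 0.13 whose libraries overlap, and autosomes showed 0.14, so this stays open. Along the chromosome the median ran from 0.29 between 13.1 and 21.8 Mb to 0.10 in the last block from 140 Mb. A biological effect of the treatment stays untested.

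Fold changes followed region strength. The median log2 fold change was -0.36 in the second decile of abundance and 0.37 in the highest, where 73.5% of regions were gene boundaries. A difference in library size stays open. For each library a slope on abundance was fitted to its log2 CPM minus the mean of the 6 libraries. Relative to that mean, the slope was -0.07, -0.10 and -0.01 in DMSO replicates 1 to 3. In OICR-9429 replicates 1 to 3 the slope was 0.10, 0.04 and 0.05. Among DMSO libraries the slope rose with depth, and the deepest OICR-9429 library had the highest slope. The shallowest OICR-9429 library, compared first, lay 0.0686 above the highest slope among the deeper DMSO libraries, a comparison that rests on 1 library. Over all 6 libraries the groups differed by 0.126, and by 0.106 at equal log2 library total (95% interval 0.0130 to 0.198), with a coefficient of 0.135 for log2 total (SE 0.0834, its 95% interval including 0). With 1 library left out the difference was 0.0666 to 0.131, and the interval included 0 in each case but the one without DMSO replicate 3. The condition that it hold without each library was set after the value over all 6 was seen. A difference in IP efficiency or background between the groups may produce such a trend. At matched read density and width, boundary regions exceeded distal regions by 0.18 more with OICR-9429 than with DMSO, against 0.44 without matching. The libraries overlapped in the matched difference (exact two-sided permutation p = 0.2). An antibody or background difference and a redistribution of the mark by the treatment therefore cannot be told apart. Input libraries and spike-in reads, which bear on this, were not used here.

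The 6 libraries can be split 3 against 3 in only 10 ways, too few for a share under 0.05. The real split called 15888 regions with TMM and 7347 with loess offsets, and 1 of the 10 splits, the real one, reached each count. The highest other split called 0 regions with edgeR under either scaling, with up to 4340 and 5501 regions at an unadjusted p under 0.05. Each other split holds libraries of both treatments on either side. A difference between the treatments then widens the spread within sides and lowers the calls. The 0 calls therefore do not measure how many calls of the real split are false. For the gene lists the real split called 2 and another split called 6, and 5 of the 10 splits called at least 2. Splits that mix the groups thus gave list calls with the preset correlation, which points to structure among the libraries that list members share.

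A total of 843 regions had a count of 0 in all 6 libraries, and 465 of them lay in 52 runs of at least 5 neighbours. Chromosome 6 held 189 of the 843 and chromosome 17 held 139, and the longest run was 23 regions on chromosome 14, from 93192790 to 94067097. These counts do not show whether reads were absent there or were not counted, and a 0 was not read as absence of the mark.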
